A study of Homo sapiens and Mus musculus with 32 samples.

How the data were processed

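KLF1 was immunoprecipitated from HuDEP and K1ER cells and sequenced with input as single reads of 50 bp, per the labels' protocols. The submitters' processing notes name FastQC 0.10.1, Trimmomatic, Bowtie2, SAMtools and HOMER, and the builds hg19 and mm9. Versions of the other tools are left out because each carries extra digits. The file headers are those of HOMER's peak caller, and the lists are named as output of an irreproducible discovery rate (IDR) step. The protocols state 2 replicates per line, while K1ER has 4 libraries of each kind, and which libraries were merged into the K1ER list is not given in the sources used here.

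Each deposited list gives 1 row per peak, called on merged immunoprecipitate against merged input, with no column for a replicate. The normalized tag count is a signal scaled by the authors to the depth of the immunoprecipitate. The total tags are whole-number counts of merged immunoprecipitate tags, as deposited. The control tags are the authors' input signal, scaled to the immunoprecipitate, per the file headers. The focus ratio is a fraction from the authors' peak caller, per the file headers. The peak score is the authors' own, used only to rank peaks within a list. The fold columns are the authors' ratios over input, over the surrounding region and over the clonal expectation, per the file headers. The p-value columns are the authors' tests against input and the surrounding region, as deposited, and none is printed here. The lowest fold over input was 4.63 in HuDEP and 4.02 in K1ER in the authors' deposited table. Tags exceeded the positions of the peak on both strands in 103 HuDEP and 7939 K1ER peaks, so duplicate tags had not been limited to 1 per position.

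The lists hold another form than was assumed when the tests were fixed before the data were examined. They have no IDR value, no score per replicate and no gene name. Replicate agreement, the relation of IDR to score, the share of peaks near transcription start sites, the share with a CACC box, enrichment of the 15 fixed gene lists, genes bound in both lines and peaks at ZBTB7A were therefore not analysed here. The last 5 also need a genome or annotation of the lists' builds, and the human gene table at hand is of another build (GRCh38.p14) and was not used for positions. The rule for named sites, fixed before the data were examined, took the 10 top peaks per line by mean replicate score. With no replicate scores, the listed peak score was used, and ties went to chromosome and position. All tests beyond the number of peaks were chosen after the lists were seen.

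The K1ER list uses sequence names of GRCm38 and reaches 156253304 on chromosome 4, unlike the mm9 of the notes. Its coordinates are given as listed. The HuDEP positions, up to 48056050 on chromosome 21, fit within hg19. Peak names carry a number per chromosome in order of score, and 88.9% of the HuDEP numbers and 84.0% of the K1ER numbers up to the highest on each chromosome are present. Peaks with other numbers were not analysed here.

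Depth was computed as total over normalized tags times 10000000, the caller's usual scale, which the headers do not state. It came to 11960245 tags in HuDEP and 80004688 in K1ER. The weakest peaks held 29 and 71 tags, a counting error of 18.6% and 11.9%. Input tags were recovered from tags over the listed fold as whole multiples of 0.213 scaled tags in HuDEP and 0.503 in K1ER. At a tolerance of 0.1 tag, 99.96% of HuDEP and 99.996% of K1ER values were whole, which puts the input depth at 56177762 and 158991828 tags. The listed input, rounded to 1 decimal, was too coarse to give the HuDEP factor. Intervals for folds are exact binomial on immunoprecipitate and input tags. These and the intervals for the share of tags in peaks treat tags as independent, so with duplicate tags kept they may be too narrow.

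Density was the number of peaks per Mb between the first and last peak of a chromosome, on the numbered chromosomes and X. It was tested with a two-sided exact binomial test per chromosome, adjusted by Benjamini-Hochberg within each line. Neighbours were counted within 10 kb of peak midpoints and compared with 1000 placements drawn uniformly, along the chromosome or within 1 Mb windows. Mean input was taken per chromosome in HuDEP autosomes and per bin of 10 Mb with at least 20 peaks in K1ER, without peaks over 5 times their chromosome's mean. The typical value was the median chromosome or bin. Intervals of ratios came from 1000 bootstrap resamples of peaks. They treat peaks as independent, so they may be too narrow where peaks of a region share its level.

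The statistics were tested on simulated data first. Over 200 uniform HuDEP lists of 5133 peaks the mean ratio of neighbours was 1.01 (SD 0.0813) and 7.00% had p below 0.05. Over 200 uniform K1ER lists of 50879 peaks the mean ratio was 1.00 (SD 0.00733) and 4.50% had p below 0.05. A first version of this check, with 1 uniform list, was too noisy to judge the HuDEP ratio and was replaced. A planted 3-fold density was recovered in both, which the way it was planted made certain. It checked the counting only, and the binomial test was not tested on simulated data. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used. Alternatives covered merging of peaks, sequences counted, height and fold floors, peaks with high input, neighbour distances, placements, loci, dense windows, and height floors or scores adjusted by input ratio.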

Results

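Binding of KLF1, an erythroid zinc-finger activator that recognises CACC boxes, was mapped by chromatin immunoprecipitation and sequencing in 2 erythroid cell lines. HuDEP (HUDEP-2) is an immortalised human line derived from cord blood progenitors. K1ER is a mouse line that lacks endogenous KLF1 and carries a tamoxifen-inducible KLF1 fused to an oestrogen receptor domain, and the K1ER cells had received 200 nM tamoxifen for 2 h. The 32 sequencing entries comprised 8 of KLF1 immunoprecipitate and 8 of input from each line. In HuDEP they came from 2 libraries of each kind run on 4 lanes, and in K1ER from 4 libraries of each kind run on 2 lanes. The series title names ZBTB7A (LRF), a repressor of fetal globin, and the question put to the data was where KLF1 bound in each line. Each line had a single merged peak list, so no value below has a replicate spread. Exact intervals cover counting error only, and bootstrap intervals cover the spread over resampled peaks.

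KLF1 peaks were far more numerous in the K1ER list than in the HuDEP list. The HuDEP list held 5136 peaks of 186 bp, and the K1ER list held 50888 peaks of 210 bp, 9.91 times as many. The K1ER immunoprecipitate was also deeper, at 80004688 tags against 11960245 in HuDEP. Peak height is given as the normalized tag count, in tags per 10000000. At a shared floor of 24.2 normalized tags, the lowest height in the HuDEP list, K1ER kept 22791 peaks, 4.44 times the HuDEP number. Peaks took up 3.13% of the HuDEP immunoprecipitate tags (exact Clopper-Pearson 95% interval 3.12 to 3.14%) and 16.5% of the K1ER tags (16.47 to 16.49%). Input tags, scaled to the immunoprecipitate's depth, amounted to 0.0901% in the HuDEP peaks and 0.632% in the K1ER peaks. The 5136 strongest K1ER peaks alone held 5.40% of the K1ER tags. The lines differ in species, depth, peak width and the form of KLF1 they carry, and no test compared their counts.

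The 10 KLF1 peaks of HuDEP with the highest scores were a trio with very high input and low focus on chromosome 21 and 7 focused peaks elsewhere. Ranked by the authors' peak score, the HuDEP peaks at ranks 1, 2 and 4 lay together on chromosome 21 (hg19), at 9825618 to 9825804, 9826286 to 9826472 and 9826849 to 9827035. They carried 926.4, 884.6 and 742.4 normalized tags, with scaled input of 56.4, 39.0 and 52.2 tags where the median HuDEP peak had 1.7. In the authors' deposited table these 3 peaks stood 19.6-fold, 27.2-fold and 17.0-fold above input. Over their surroundings they stood 8.35-fold, 7.91-fold and 6.48-fold there, where the other 7 peaks stood 198-fold to 580-fold. The 3 peaks lie close together, so tags of each may enter the surroundings of the others. Whether the trio marks KLF1 binding was not tested. The HuDEP peak at rank 3, on chromosome 20 at 57226152 to 57226338, had 857.0 normalized tags and 4.00 scaled input tags, also above the HuDEP median. Its fold over input in the authors' deposited table was 253 (exact counting interval 161 to 423). The other 6 of the 10 strongest HuDEP peaks lay on chromosomes 8 (95731970 to 95732156), 17 (80023634 to 80023820), 11 (47429932 to 47430118), 19 (1383759 to 1383945), 9 (140317548 to 140317734) and 5 (177026975 to 177027161). These 6 had 5.7 to 7.7 scaled input tags, above the HuDEP 95th percentile of 4.3. Their folds over input ranged from 93.8 to 131 in the authors' deposited table, and their focus ratios, the fraction of tags placed around the centre as a point source would give, from 0.936 to 0.969. The chromosome 21 trio had focus ratios of 0.599 to 0.650.

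In K1ER the strongest KLF1 peak lay on chromosome 13 at 48968023 to 48968233, with 502.9 normalized tags. It stood 286-fold over input in the authors' deposited table (exact counting interval 197 to 431). The K1ER peaks at ranks 2 and 3, on chromosome 5 at 146794940 to 146795150 and chromosome 15 at 67176702 to 67176912, had 409.3 and 408.3 normalized tags. The other 7 of the 10 strongest K1ER peaks had 372.3 to 405.2 normalized tags, and lay on chromosomes 8 (120276455 to 120276665 and 123859414 to 123859624), 5 (149229123 to 149229333), 1 (37864802 to 37865012, 86472248 to 86472458 and 160906176 to 160906386) and 15 (38473605 to 38473815). All 10 of these K1ER peaks lay in 10 Mb bins with raised input, where 21.1% of the whole K1ER list lay. Of the 100 K1ER peaks with the highest scores, 46 lay in such bins (exact Clopper-Pearson 95% interval 36.0 to 56.3%). With the score divided by the input ratio of the bin, only 1 of the 10, the chromosome 13 peak, stayed among the first 10, against 8 of 10 in HuDEP with chromosome ratios. The first 10 of K1ER then included 4 peaks from thin chromosome 3 bins with lowered input. The median local background of the K1ER immunoprecipitate rose less than the mean input, by 1.21 times in raised bins. With scores there divided by that ratio 5 of the 10 stayed. K1ER positions are as listed. The submitters' processing notes name mm9, but the list runs to 156253304 on chromosome 4 and uses sequence names of the later GRCm38 build, so these positions are given on the list's own scale. No peak was tied to a gene, because no annotation of either build was used here.

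Peak heights were spread differently in the 2 lines. HuDEP had a separate group of high KLF1 peaks, while K1ER heights fell off steadily. HuDEP counts dropped to 46 peaks between 152 and 181 normalized tags (exact Poisson interval 33.7 to 61.4) and rose again to 80 between 256 and 304 (63.4 to 99.6). The same K1ER classes held 253 and 67 peaks. Peaks of 200 or more normalized tags made up 5.84% of the HuDEP list (300 peaks) and 0.593% of the K1ER list (302 peaks), which reaches lower heights. At the shared height floor the K1ER share was 1.33%. These bounds were chosen after the heights were seen.

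**Figure D1:**
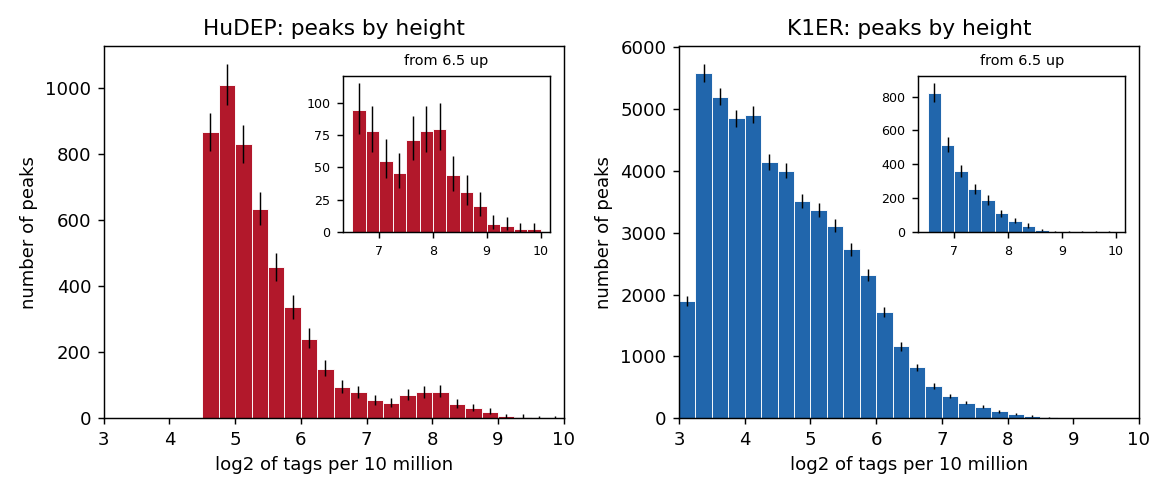
Number of KLF1 peaks by height (log2 of normalized tags, in steps of 0.25) in HuDEP and K1ER, with exact Poisson 95% intervals as error bars and the high end enlarged in the insets. HuDEP counts fall to 46 and rise again to 80 peaks, whereas K1ER counts keep falling over the same heights.

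Higher HuDEP peaks were more focused, and higher K1ER peaks less so. The median focus ratio in HuDEP rose from 0.816 (interquartile range 0.75 to 0.881) below 40 normalized tags to 0.929 (0.892 to 0.947) at 200 or more. In K1ER it fell from 0.837 (0.781 to 0.876) to 0.734 (0.695 to 0.771). Across peaks, which are not independent replicates, the rank correlation of focus ratio with height was 0.227 in HuDEP and -0.218 in K1ER. The surroundings differed as well. For peaks of 200 or more normalized tags, the median fold over the surrounding region in the authors' deposited table was 147 in HuDEP and 24.3 in K1ER. Tags of neighbouring peaks may enter the surrounding region and were not taken out. Neighbours within 10 kb were more common in K1ER (73.4% of all peaks) than in HuDEP (20.05%). With fold over input in place of height the correlation was 0.122 in HuDEP and -0.135 in K1ER, and at the shared height floor the K1ER value was -0.394. Focus ratio and fold were computed by the authors within each list at its own peak width, so the 2 lists give directions and no common scale.

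**Figure D2:**
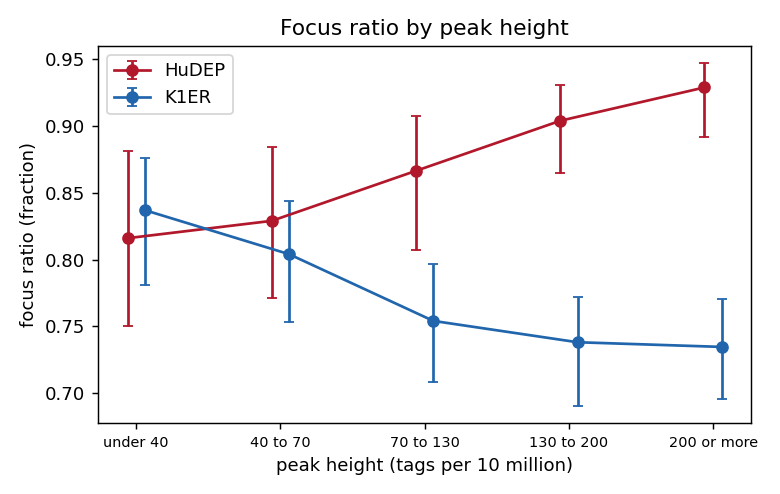
Median focus ratio (fraction of tags, points) with interquartile range (bars) for peaks grouped by height (normalized tags) in HuDEP and K1ER. The HuDEP median goes from 0.816 to 0.929 while the K1ER median goes from 0.837 to 0.734.

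KLF1 peaks were unevenly shared among chromosomes in both lines. Human chromosome 19, a gene-rich chromosome that carries both KLF1 and ZBTB7A, stood far above the rest of the HuDEP list, with 568 peaks or 9.67 per Mb (exact Poisson 95% interval 8.89 to 10.5). That was 5.50 times the number expected from its length (two-sided exact binomial test, Benjamini-Hochberg adjusted p = 3.2e-229). Chromosome 22 followed with 3.94 peaks per Mb (3.30 to 4.67) and chromosome 17 with 3.60 (3.20 to 4.05). Chromosomes X and 4 were lowest, at 0.279 and 0.943 peaks per Mb. In K1ER, mouse chromosome 11 was densest, with 4310 peaks or 36.3 per Mb (35.2 to 37.4), 1.82 times expectation (exact binomial test, adjusted p = 3.7e-295). Mouse chromosomes 19 and 17 followed with 28.9 and 25.6 peaks per Mb, and X was lowest with 6.23.

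Of the 23 HuDEP chromosomes tested, 7 held more peaks than their length gave and 9 held fewer. Of the 20 K1ER chromosomes, 10 held more and 8 fewer. Peaks close together are not independent, so peaks within 10 kb were joined into loci and counted once. Neighbours within 50 kb were also in excess (2.17 times in HuDEP and 1.1 times in K1ER), so loci may stay partly dependent. The p-values measure departure from even placement by length and cover no replicate spread. By loci, HuDEP had 6 chromosomes above and 9 below expectation, and chromosome 19 stayed at 4.63 times expectation (exact binomial test, adjusted p = 5.0e-145). HuDEP chromosome 8 was no longer called above, at 1.09 times expectation (exact binomial test, adjusted p = 0.22). It held 30 peaks between 145 and 146 Mb and 19 between 144 and 145 Mb. By loci, K1ER had 8 above and 8 below, with chromosome 11 at 1.63 times expectation (exact binomial test, adjusted p = 2.7e-88). HuDEP chromosomes 6, 8, 19 and 21 also had raised input at their peaks, at 1.52, 1.39, 1.44 and 1.45 times the typical chromosome. With the height floor of chromosome 19 raised by its input ratio, its density was 3.61 times expectation. The same step took chromosome 6 from 1.24 to 0.719 times expectation, chromosome 8 from 1.16 to 0.728 and chromosome 21 from 1.46 to 0.988. In either line, a floor raised on a single chromosome can only lower its share of peaks. HuDEP peaks crowd near their floor of 24.2 normalized tags, with a median of 36.8, so a fall was likely whatever the cause. The step therefore cannot tell whether the 3 HuDEP excesses rested on the lowest peaks more than on others, or whether raised input made them. In K1ER, chromosomes 13 and 15 were above expectation by peaks (1.09 and 1.18 times), with input at 1.41 and 1.38 times the typical chromosome. By loci they were at 1.23 and 1.08 times expectation (exact binomial test, adjusted p = 1.1e-13 and 0.020). Raised floors were applied to peaks and not to loci. With floors raised by their input ratios, chromosomes 13 and 15 went to 0.841 and 0.997 times. Floors raised by the smaller rise of the K1ER local background, 1.21 times, gave 0.958 for chromosome 13 and 1.08 for chromosome 15, which then stayed above expectation (exact binomial test, adjusted p = 7.9e-04). Mouse chromosome 11 had typical input (1.00 times), and mouse X had the lowest (0.831 times). HuDEP X was left out of the input means. Whether lowered input bears on the low density of X was not tested in either line.

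**Figure D3:**
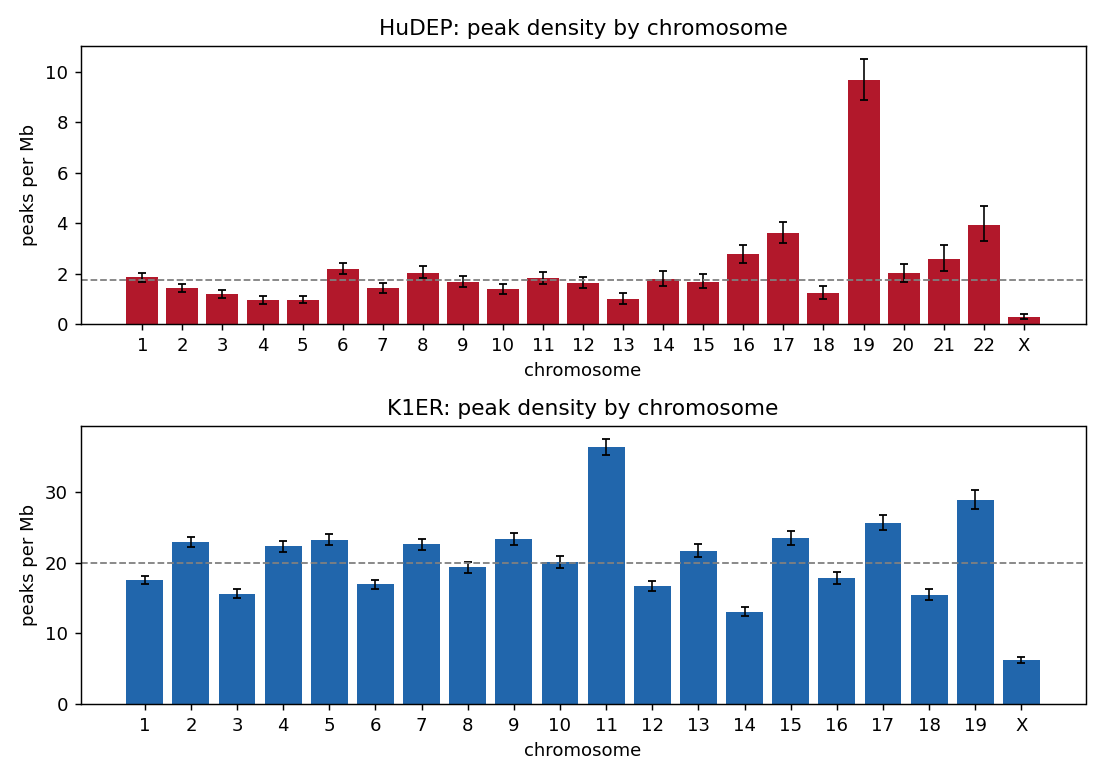
KLF1 peaks per Mb on each chromosome (bars) in HuDEP and K1ER, with exact Poisson 95% intervals and the density of the whole list as a dashed line. Human chromosome 19 reaches 9.67 peaks per Mb and mouse chromosome 11 reaches 36.3.

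KLF1 peaks lay in clusters in both lines. In HuDEP 20.05% of peaks had another within 10 kb, against 5.20% (SD 0.421) in 1000 random placements along the chromosomes, a ratio of 3.85 (permutation p = 0.001, one-sided, the smallest these placements can give). In K1ER 73.4% of peaks had such a neighbour, against 34.8% (SD 0.265), a ratio of 2.11 (permutation p = 0.001). Placements within each peak's own 1 Mb window, which keep the regional density, lowered the ratios to 1.98 in HuDEP and 1.29 in K1ER. At the shared height floor the K1ER ratio was 3.37. For neighbours within 50 kb the ratios were 2.17 in HuDEP and 1.1 in K1ER along the chromosomes, and 1.3 and 1.04 within 1 Mb windows. In K1ER 95.6% of peaks had a neighbour within 50 kb, against 86.7% along the chromosomes and 91.7% within windows. Those K1ER ratios had little room to rise, and a ratio depends on the expected share, so the 2 lines cannot be ranked by it.

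The HuDEP peaks formed 4569 loci, of which 4104 held a single peak and 10 held 5 or more. The largest 2 had 8 peaks each, on chromosome 8 at 145002723 to 145027087 and on chromosome 19 at 1237972 to 1275615. A chromosome 19 locus at 56146195 to 56165780 had 5 peaks that summed to 1022.5 normalized tags. The K1ER peaks formed 24600 loci, of which 13521 held a single peak and 264 held 10 or more. The largest K1ER locus spanned 148.0 kb of chromosome 17 (29373863 to 29521859) with 39 peaks, and the next spanned 127 kb of chromosome 7 (63896307 to 64023726) with 30 peaks. Among 1 Mb windows, the densest HuDEP window held 41 peaks between 1 and 2 Mb of chromosome 19, where the median window with a peak held 2. The densest K1ER window held 170 peaks between 80 and 81 Mb of chromosome 10, against a median of 15. These regions were singled out after their counts were seen.

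Input at peaks, the background of the measurement, changed by region in K1ER and between chromosomes in HuDEP. In K1ER 46 of 261 bins of 10 Mb had a mean input at least 25% above the typical bin and 5 at least 25% below. Raised runs covered most of mouse chromosomes 1, 13 and 15 and parts of chromosomes 3, 5, 8 and 16. Chromosome 3 went from 1.49 times the typical input between 80 and 130 Mb to 0.572 times between 140 and 160 Mb. K1ER peaks in raised bins had 1.45 times the input of the other peaks (bootstrap 95% interval 1.43 to 1.46), in part because the bins were picked by that input.

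**Figure D4:**
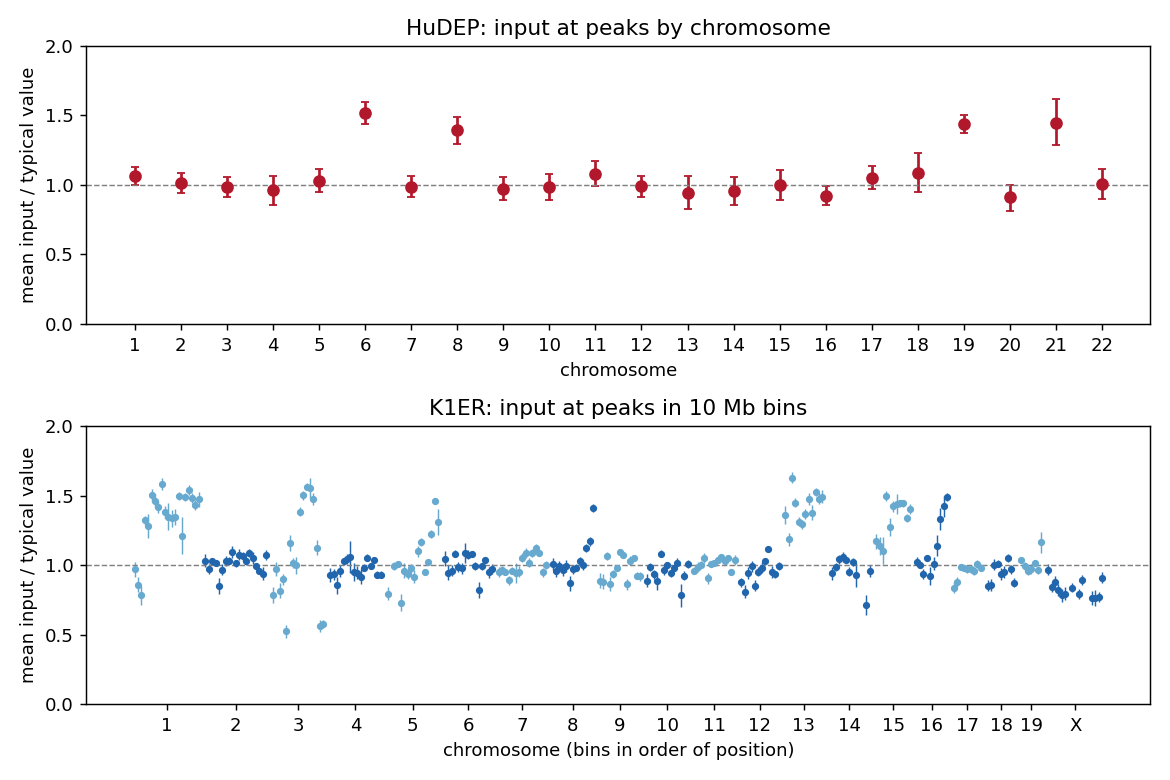
Mean scaled input per peak divided by its typical value, for each HuDEP autosome (bootstrap 95% intervals) and for 10 Mb bins along the K1ER chromosomes (bars are standard errors). HuDEP chromosomes 6, 8, 19 and 21 lie between 1.39 and 1.52, and the long runs of raised K1ER bins on chromosomes 1, 3, 13 and 15 have means of 1.42 to 1.49, with single bins on either side.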

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

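The regions and chromosomes were singled out after their input was seen. Of the tests, those of an effect of the input libraries alone and of stronger peaks were set before their values were seen, and the bound for more copies was tightened afterwards.

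Input tags at KLF1 peaks were raised over long regions in K1ER and, as a mean, over whole chromosomes in HuDEP. Their regional level lies outside the measurement of binding, but it enters the folds over input, and it bears on the ranking of K1ER peaks and on the density of chromosomes. In K1ER the mean was 1.44 times the typical bin at 30 to 140 Mb of chromosome 1, 1.49 at 150 to 200 Mb of chromosome 1, 1.49 at 80 to 130 Mb of chromosome 3, 1.45 at 140 to 160 Mb of chromosome 5, 1.44 at 20 to 120 Mb of chromosome 13, 1.42 at 30 to 110 Mb of chromosome 15 and 1.47 at 70 to 100 Mb of chromosome 16. In HuDEP it was 1.52 times the typical chromosome on chromosome 6, 1.39 on chromosome 8, 1.44 on chromosome 19 and 1.45 on chromosome 21. HuDEP input was not binned, so an even rise along these chromosomes was not shown. Median input was 1.8 at 145 to 146 Mb and 1.5 at 144 to 145 Mb of chromosome 8, against 2.1 for that chromosome. It was 1.7 at 1 to 2 Mb of chromosome 19 and 2.1 to 2.3 in its other windows among the 10 densest, against 2.3 for that chromosome.

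An effect of the input libraries alone was argued against, because the immunoprecipitate's own median local background was also higher there. It rose by 1.49 times in HuDEP (interval 1.44 to 1.54) and 1.21 times in K1ER (1.18 to 1.23), pooled over the raised chromosomes or bins. Tags of neighbouring peaks may enter this background and were not taken out. The K1ER value only just reached the bound set beforehand, which lay inside its interval. An effect of the input libraries on part of the K1ER rise therefore stays open. Both intervals resample single peaks, while peaks of a region share its level, so they may be too narrow. Stronger peaks as the whole source were argued against too, since among peaks at or below the median height the input ratio was still 1.49 in HuDEP and 1.42 in K1ER. The input of these same peaks helped to pick the regions, so the ratios tend to run high. For HuDEP, more copies of chromosomes 6, 8, 19 and 21 in the cells are a candidate explanation, as the pooled median local background rose about as much as the mean input did (1.45 times). Of the 1332 peaks behind the input ratio, 567 lay on chromosome 19, and the pooled background cannot show extra copies of any chromosome by itself. For K1ER the rise in median local background, 1.21 times, fell short of the 1.45 times in mean input, so more copies of those regions stay open. GC content and mappability were not tested, since no genome was used here, and no biological explanation given by the design was tested.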

How the results depend on the processing

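Alternatives that merged peaks (overlapping, or within 500 bp) or kept only numbered chromosomes and X and Y were planned, and all others here were chosen after seeing the data. Of the alternative values, 50 had the same direction and side of the threshold or lay within their range, 8 moved and 9 reversed. With the height floor raised by the input ratio, 5 chromosomes above expectation went below 1, to 0.719 (6), 0.728 (8) and 0.988 (21) in HuDEP and 0.841 (13) and 0.997 (15) in K1ER, by the loss of their lowest peaks. With the floor raised by the local background ratio (1.49 in HuDEP, 1.21 in K1ER), they were at 0.719 (6), 0.628 (8), 0.928 (21) and 0.958 (13), while chromosome 15 stayed above at 1.08. Of the 10 named K1ER peaks, 1 stayed among the first 10 with scores divided by the input ratio and 5 with the local background ratio. With floors raised on all chromosomes of raised input, 7 HuDEP chromosomes were again above expectation, but only 4 of them were above before (chromosomes 1, 11 and 20 in place of 6, 8 and 21), and 8 were below, 6 of them as before. In K1ER 9 were above and 9 below, 8 of each as before. At the shared height floor K1ER had 22791 peaks in place of 50888, and its correlation of focus ratio with height went to -0.394, both on fewer, higher peaks. The 5136 strongest K1ER peaks held 5.40% of tags in place of 16.5%, by construction. Without 21 peaks of high input, the HuDEP share of tags in peaks was 3.07% in place of 3.13%. With fold over input in place of height, the focus correlation was 0.122 in HuDEP and -0.135 in K1ER, and the cause was not tested. Chromosome 19 in HuDEP stayed between 3.38 and 6.18 times expectation and chromosome 11 in K1ER between 1.59 and 1.86. The neighbour ratio ranged from 1.3 to 5.34 in HuDEP and from 1.04 to 3.37 in K1ER, with permutation p = 0.001 in each. The lowest K1ER ratio set 95.6% against an expected 91.7%, so it had little room to rise. For HuDEP, the shared floor changed nothing because it is that list's own. The alternatives set beforehand on IDR thresholds, on replicate scores, on leave-one-out choices, on distance to transcription start sites, on CACC boxes, on gene lists, on genes bound in both lines and on ZBTB7A were not run and give no value. No paired analysis was possible because each line's list is merged and has no value per replicate. Depth limits the weak end of the HuDEP list most, where a peak rests on 29 tags.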

Other observations

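All tests here were chosen after the density of chromosome 19 and the input at high peaks were seen. For more copies of chromosome 19 alone, the bound was set before the value it is held against.

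Chromosome 19 led the HuDEP list by density. More copies of chromosome 19 as the whole source were argued against, because with its height floor raised by its input ratio it still had 6.08 peaks per Mb (exact Poisson interval 5.46 to 6.74), above the 3.94 of chromosome 22. A few dense windows were argued against as well, since without its 5 densest windows it had 8.11 peaks per Mb. Gene density, for which chromosome 19 is known, was not tested.

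In HuDEP, median scaled input went from 1.5 tags at KLF1 peaks under 40 normalized tags to 3.40 at peaks of 200 or more, where K1ER went from 9.10 to 11.1. More copies of the chromosomes holding the high peaks were argued against, with a ratio of 2.21 after division by the chromosome's mean. Immunoprecipitate reads counted in the input library may be a source, as the excess was 0.564% of immunoprecipitate tags at 130 to 200 normalized tags and 0.559% at 200 or more, a ratio of 0.991 (interval 0.850 to 1.55). Repeated sequence at high peaks stays open, since leaving out the 22 peaks of over 10 scaled input tags left the ratio at 2.27 and could not have moved a median, and so does open chromatin, which was not tested.

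High input marked other single HuDEP peaks. On chromosome 1 the peak at 156186405 to 156186591, at rank 14 by score, had 61.7 scaled input tags and a focus ratio of 0.646. Also on chromosome 1, the peak at 91852802 to 91852988 had 92.2 scaled input tags and stood 5.37-fold over input in the authors' deposited table. On chromosome 8 the peak at 70602317 to 70602503 had 65.6 scaled input tags, was 5.41-fold over input and was 493-fold over its surroundings in the authors' deposited table. In K1ER 8 peaks lay on sequences not placed on a chromosome, and the strongest of them had 86.5 scaled input tags.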
